A study of Gallus gallus with 6 samples.

How the data were processed

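The series examined where the transcription factor TCF21 binds the genome of chicken preadipocytes, the fibroblast-like precursors of fat cells. TCF21 is a basic helix-loop-helix factor, a class of proteins that bind short E-box sequences as dimers. The cells came from adipose tissue and carried a lentiviral construct that expresses TCF21 stably. They were kept for 24 h in medium with 300 µM oleic acid, a fatty acid used to induce fat cell differentiation in chicken cells. Chromatin was sonicated and immunoprecipitated with an antibody against the HA epitope tag. The labels give 6 samples, 3 TCF21 immunoprecipitations and 3 input DNA samples, and do not say whether the samples of a group came from separate cultures. Each SD below therefore measures the spread between these samples, which may be technical. The protocol in the labels also names a control rabbit IgG, and no IgG sample was analysed here.

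The processed data are 3 peak lists, 1 per immunoprecipitation and none pooled, as the peak names in the lists show. They are called lists 1, 2 and 3 by the number in those peak names. That number was not matched to the replicate number of a sample, and each list was treated as an unnumbered sample of the immunoprecipitation group. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.3a, MACS2, bedtools and HOMER without the role of each. Per the file headers, the columns are those of a MACS2 peak table. The pileup is a deposited signal, the number of fragments stacked at the peak summit, and 100% of its values are whole numbers. The fold enrichment is a deposited ratio of the pileup to the local control level, with a pseudocount of 1 added to both. The significance of each peak is deposited as the −log10 of its p-value and of its q-value. The width of each peak in bp is deposited as well. The genome build, the peak calling threshold and the library that served as the control of each list are not given in the sources used here. Of the 1757 scaffold names in the lists, 1645 start with AADN04, which narrows the assembly without naming the build. The control is called input below because the labels name input DNA as the companion of the immunoprecipitations. The smallest −log10 p in the lists was 2.00, so the lists end at a p-value of 0.01, and they hold peaks with q-values above 0.05.

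The input level at each summit was recovered from the deposited values as (pileup + 1) / fold enrichment − 1. The Poisson p-value recomputed from the pileup and this level matched the deposited one within 1% plus 0.01 on the −log10 scale for 99.9% of the peaks of each list. Input levels are given relative to the mean over the autosomal peaks of the same list. Total read numbers are not in the peak lists, so sequencing depth is unknown and no counting interval was computed. Low values are coarse: the smallest pileup was 3 or 4 fragments, and the input level had a floor in each list (0.948, 0.924 and 0.744 fragments in lists 1, 2 and 3), which the peak caller sets where few control reads are found.

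Peaks of different lists that overlapped by at least 1 bp were joined into regions, and a region with a peak from all 3 lists was called reproducible. Where a list had several peaks in a region, its strongest one by fold enrichment was used. Expected overlaps came from 100 seeded shuffles of each list within its chromosomes with bedtools 2.31.1. Median fold enrichment in and outside reproducible regions was compared in each list with a two-sided permutation test of 100000 resamples, Benjamini-Hochberg adjusted over the 3 lists. The density of regions was related to chromosome span, taken as the end of the last peak on the chromosome because no genome was used here, over the 33 chromosomes with a number or letter. This used Pearson's r and Spearman's rho with permutation p-values of 100000 resamples, adjusted over the 16 tests of that family. Correlations between lists run across regions, which are not independent replicates, and carry no p-value. Steps in the input level were searched on chromosomes of at least 10 Mb by recursive splitting, keeping a split where both sides were at least 5 Mb wide and their mean log2 levels differed by at least 0.25. On simulated lists of 24000 peaks, the region step found 5000 of 5000 planted shared regions, which were placed well apart from other sites. Input levels drawn separately were recovered within 1% for 100% of values, which checks only the arithmetic of the formula. Step finding was run on the peak positions of chromosome 2 in list 1, with input levels shuffled along it. There, 1 large planted step was found 57.0 kb from its place, with 0 steps where none was planted. Shuffling removes the regional trends of real input levels, so this gives no precision or false positive rate for real chromosomes. Under no difference, 7.00% of 200 simulated median tests and 2.50% of 200 rank correlations gave a p-value under 0.05, and 99.5% of the median tests did so with a 1.5-fold change. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

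The lists name no genes, and the gene table at hand belongs to another assembly (GRCg7b) than can be matched to these positions. For that reason the share of regions at promoters, the E-box and 16 other motifs and the 16 gene lists planned before the data were examined were not run, and the rule for named genes had no gene to act on. The rule planned was the 12 genes with the highest mean fold enrichment at a reproducible region and the 6 genes with the most regions. In their place, and chosen after the data were seen, the 12 reproducible regions with the highest mean fold enrichment and the 6 windows of 100 kb with the most regions are named by position. Positions are those of the deposited lists, counted from 1. Alternatives were another definition of overlap, stricter peak thresholds, fewer lists, another measure of strength, subsets of chromosomes, and leaving out each list in turn.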

Results

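TCF21 occupancy was measured by chromatin immunoprecipitation and sequencing in chicken preadipocytes that stably overexpress the factor, after 24 h with 300 µM oleic acid. The question stated for the series is where TCF21 binds in these cells. There were 3 immunoprecipitated samples and 3 input DNA samples, and each immunoprecipitation gave 1 peak list. Lists 1, 2 and 3 held 59501, 55895 and 57436 peaks. The peaks had median widths of 363, 356 and 335 bp and covered 25.8, 23.7 and 23.0 Mb. The median pileup at the summit was 15 fragments in list 1, 14 in list 2 and 12 in list 3. The median fold enrichment over input, a value of the authors' peak caller, was 5.30, 5.22 and 5.13, and the highest values were 99.6, 124 and 102. The lists were deposited down to a p-value of 0.01, and 95.6%, 94.8% and 90.4% of their peaks had a q-value of at most 0.05. The total number of reads per sample is unknown and pileups were not scaled for it, so pileups set side by side or averaged over lists include any difference in depth.

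The 12 most enriched regions shared by the lists lay on 11 chromosomes, and their mean fold enrichment over input ran from 71.8 to 91.3. The genome build of the positions is not given in the sources used here. The highest mean was at chromosome 18, 9937816 to 9939820, with a fold enrichment of 91.3 ± 18.7 (SD, n = 3) and a pileup of 225 ± 14.3 fragments. The region at chromosome 13, 17861663 to 17862609, followed with 89.4 ± 13.9, and its 3 summits lay within 2 bp of each other. The region at chromosome 25, 1704415 to 1705535, had a mean of 86.0 ± 45.7, which spanned 35.5 in list 1 to 124 in list 2, while its pileup spanned 245 to 273 fragments. The region at chromosome 6, 2094696 to 2096012, had the smallest spread of the 12, at 80.7 ± 6.63. Chromosome Z, one of the sex chromosomes of birds, held a pair of these regions, at 18205077 to 18205926 with 79.2 ± 10.8 and at 2135586 to 2137067 with 71.9 ± 21.8. The region at chromosome 1, 6894331 to 6895663, had 75.2 ± 12.7, and that at chromosome 26, 785052 to 786244, had 74.2 ± 37.3. The remaining regions were at chromosome 20, 10209195 to 10210190 (72.9 ± 22.2), chromosome 8, 2230719 to 2231892 (72.8 ± 31.2), chromosome 4, 85383708 to 85384752 (71.9 ± 8.27), and chromosome 3, 10086542 to 10087405 (71.8 ± 19.0). The input level was at its floor in all 3 lists at the first of the regions on Z, in lists 1 and 2 at the region on chromosome 13 and in list 3 at the second region on Z, so the fold enrichments there were set by that floor. Means that followed each other in this order differed by less than the SD of either region, so the order is not resolved. The highest mean pileup was at another region, at chromosome 20, 13844835 to 13846272, with 267 ± 22.0 fragments and a fold enrichment of 64.2 ± 20.7. The region at chromosome 24, 1267032 to 1267931, had 266 ± 17.4 fragments and was higher in lists 2 and 3, so this order is not resolved either.

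**Figure D1:**
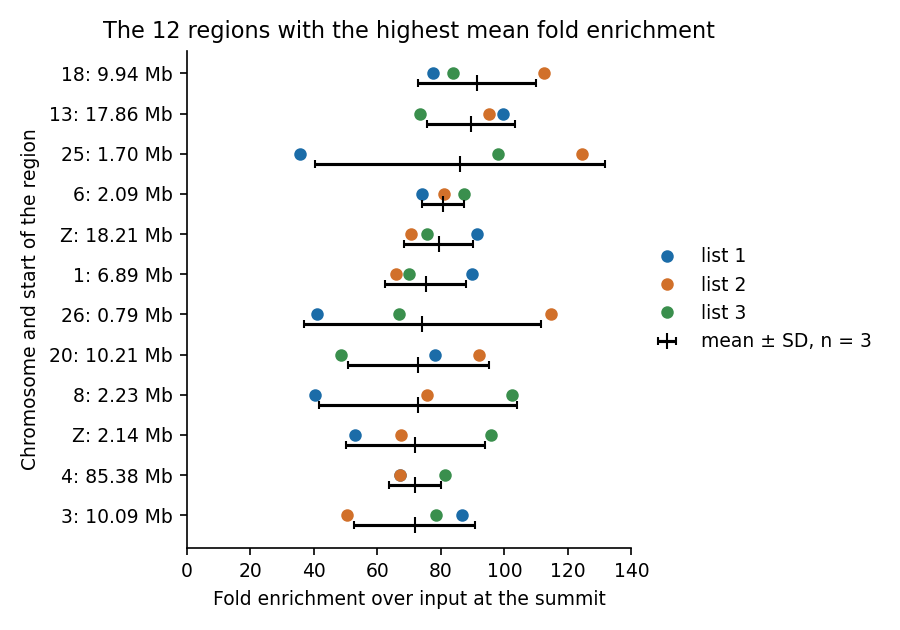
Fold enrichment over input at the summit (x axis, a ratio without unit) of the 12 regions with the highest mean (y axis, chromosome and start in Mb). Points are the 3 peak lists and bars the mean ± SD; the region on chromosome 25 runs from 35.5 to 124, while that on chromosome 6 stays within 74.1 to 87.3.

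The peaks of the 3 lists fell into 80554 regions, of which 37420 (46.5%) held a peak of every list. After shuffling the peaks within their chromosomes, 441 ± 18.7 regions were shared by all lists (mean and SD of 100 shuffles, range 386 to 486). Regions of 2 lists numbered 13897, against 7736 after shuffling, and regions of a single list numbered 29237, against 155385. A peak of one list overlapped a peak of another in 74.7 ± 2.27% of cases (SD over 6 ordered pairs of lists, range 72.3% to 78.6%), and in 5.34 ± 0.0499% after shuffling. The shuffles placed peaks anywhere on a chromosome, so any preference for places that the lists share gives an excess over them. The excess therefore does not by itself separate TCF21 binding from a background common to the lists. The 37420 reproducible regions had a median width of 542 bp, with an interquartile range of 418 to 743 bp, and covered 23.5 Mb. The widest, at chromosome 2, 9634783 to 9638650, was 3868 bp long, held 6 peaks and had a fold enrichment of 47.3 ± 11.3 (SD, n = 3). Within reproducible regions the summits of 2 lists were a median of 25.3 ± 0.577 bp apart (SD over 3 pairs of lists), and 90.1% were within 100 bp. In the 8781 regions with a fold enrichment of at least 10 in every list, the median distance was 13 bp and 98.1% of summits were within 100 bp.

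**Figure D2:**
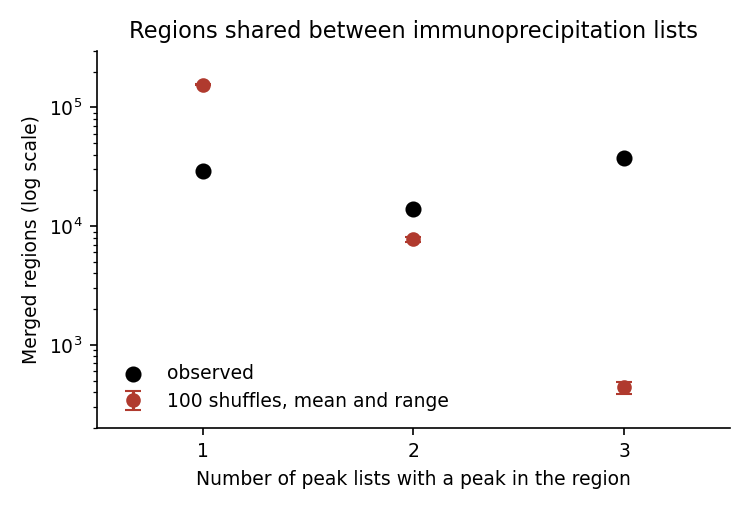
Number of merged regions (y axis, log scale) with a peak in 1, 2 or 3 of the peak lists (x axis). Black points are the observed counts and red points the mean of 100 shuffles, with bars for their range; regions in all 3 lists numbered 37420 observed and 441 shuffled.

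Reproducible peaks were more enriched than the rest in each of the 3 lists. Their median fold enrichment was 7.53 in list 1, 7.03 in list 2 and 6.90 in list 3, and that of the other peaks was 3.72, 3.65 and 3.44. The difference was 3.55 ± 0.233 (mean and SD, n = 3), with p = 1e-05 in every list (two-sided permutation test, adjusted p = 1e-05), the smallest value that 100000 resamples can give. Peaks of one list are not independent samples, so this p-value describes the peaks of that list. A reproducible peak had to be called in every list, and peaks near the calling limit drop out more easily. A difference in this direction was therefore largely built in, and the p-value adds no separate support. The median pileup of reproducible peaks was 22, 20 and 17 fragments, against 9, 9 and 7 for the others. They were also wider, with medians of 435, 416 and 397 bp against 266, 255 and 237 bp, which makes an overlap easier. The share of peaks in reproducible regions rose with fold enrichment, from 25.7 ± 3.56% in the lowest decile of a list to 61.6 ± 4.38% in the fifth, 90.3 ± 2.13% in the seventh and 99.7 ± 0.116% in the ninth decile (SD, n = 3). In the highest decile it was 100% in all 3 lists. Of the 10783, 8192 and 10262 peaks found in list 1, 2 or 3 alone, 1 in each list had a fold enrichment of at least 10, and their medians were 3.53, 3.44 and 3.35.

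**Figure D3:**
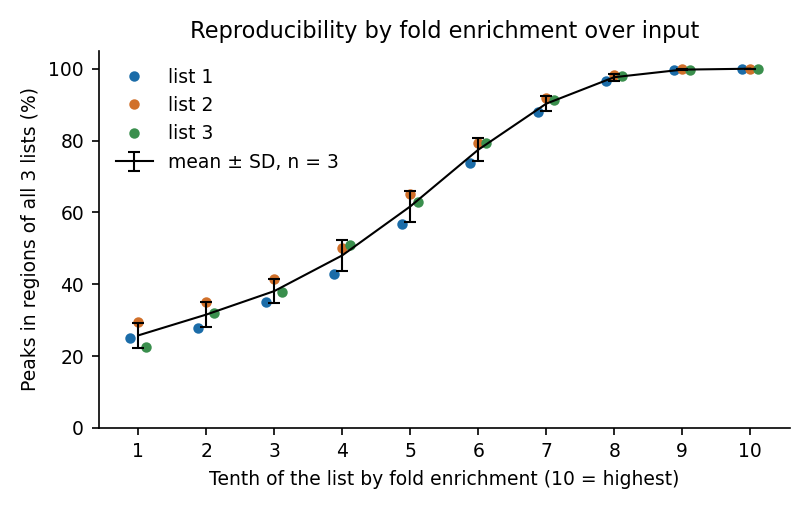
Percent of peaks that lie in regions of all 3 lists (y axis) by decile of fold enrichment within a list (x axis, 10 is the highest). Coloured points are the lists and the line with bars is the mean ± SD of 3 lists; the share goes from 25.7% in the lowest decile to 100% in the highest.

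Across the 37420 reproducible regions, the fold enrichment of 2 lists had a Spearman's rho of 0.773 ± 0.00397 and, on the log2 scale, a Pearson's r of 0.820 ± 0.00631 (SD over 3 pairs of lists). The pileup of the same regions had a rho of 0.894 ± 0.00259 and the input level at the summit one of 0.381 ± 0.0137. These values are across regions, which are not independent replicates. The identity of the strongest regions depended on the measure. Of the 100 regions with the highest fold enrichment in one list, 30.7 on average were among the highest 100 in another list. By pileup, 80.3 of 100 were shared. Of the highest 12 in one list, 1.33 on average were among the highest 12 in another list by fold enrichment and 10.7 by pileup. The 12 regions named above by their mean shared 2 with the 12 highest by mean pileup, and those on chromosomes 25, 8 and 26 ranked 1121, 719 and 665 by fold enrichment in list 1.

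Reproducible regions were denser on small autosomes than on large ones, and least dense on the sex chromosomes. The 5 autosomes of at least 50 Mb held 32.5 regions per Mb, the 6 of 20 to 50 Mb held 41.8, the 13 of 5 to 20 Mb held 50.0 and the 7 smaller ones held 48.7. Chromosome Z held 1691 regions, or 20.6 per Mb, and chromosome W held 13, or 3.41 per Mb. The value of W rests on 19, 25 and 19 peaks in lists 1, 2 and 3. The same classes had 50.2 ± 1.73, 63.4 ± 2.06, 75.6 ± 2.89 and 73.7 ± 2.05 peaks per Mb, with 33.0 ± 2.33 on Z and 5.51 ± 0.909 on W (SD, n = 3). The differences between the 3 classes of autosomes of at least 5 Mb, and between these and the sex chromosomes, exceeded the spread between lists. Chromosomes 28 and 26 reached 65.4 and 64.3 regions per Mb, while chromosomes 1 and 2 had 30.8 and 30.9. Single chromosomes of different classes overlapped. The short chromosomes 16, 25, 27 and 22 had 21.9, 33.7, 38.4 and 38.6 regions per Mb, fewer than the 40.1 of the large chromosome 5. Chromosome 30 had 142 per Mb, from 3 regions on 0.021 Mb. Over 33 chromosomes, density fell with chromosome span by rank (Spearman's rho = −0.469, permutation p = 0.0062, adjusted p = 0.0142) but not past the threshold by Pearson's r (−0.348, permutation p = 0.0618, adjusted p = 0.0824). Without the 2 chromosomes farthest from the median span, rho was −0.407 (permutation p = 0.0233, adjusted p = 0.0373) and r was −0.346. Among the 25 chromosomes of at least 5 Mb, rho was −0.811 (permutation p = 1e-05, adjusted p = 8e-05). This cut goes by span alone: it left out the dense chromosome 28 with 324 regions and kept chromosome 27 with 216. Among the 11 autosomes of at least 20 Mb rho was −0.736 (permutation p = 0.0124, adjusted p = 0.0220), and among the 20 shorter ones it was −0.277 (permutation p = 0.238, adjusted p = 0.238).

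**Figure D4:**
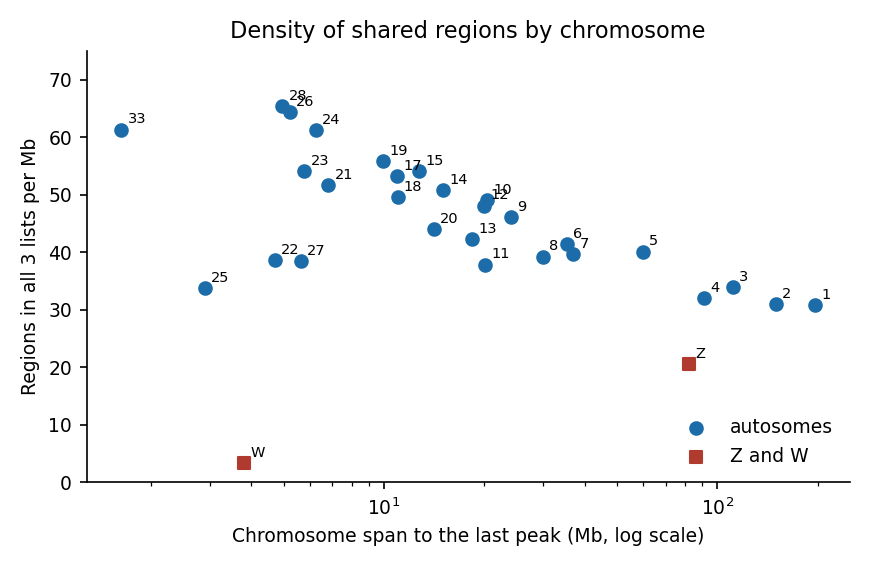
Reproducible regions per Mb (y axis) against chromosome span to the last peak in Mb (x axis, log scale), with one point per chromosome of at least 1 Mb. Blue circles are autosomes and red squares the sex chromosomes; chromosome 1 has 30.8 regions per Mb, chromosome 28 has 65.4, Z has 20.6 and W has 3.41.

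Regions were clustered along the chromosomes. Another reproducible region lay within 10 kb of 71.5% of them, against 52.3 ± 0.309% when regions were shuffled within chromosomes (mean and SD of 100 shuffles, highest 53.1%). Of 10193 windows of 100 kb, 767 held at least 10 regions, against 92.9 after shuffling (highest 113). A further 2211 (21.7%) held none, without a shuffled value to compare. The shuffles placed regions anywhere on a chromosome, so broad differences in density along it and stretches without usable sequence also count as clustering here. The densest window was at chromosome 1, 54100001 to 54200000, with 31 regions, and the highest count in any shuffled window was 20. This window held 40.7 ± 2.08 peaks per list, and its strongest region, at 54179766 to 54180827, had a fold enrichment of 36.4 ± 13.3 (SD, n = 3). Chromosome 3 had windows with 28 regions at 27700001 to 27800000 and with 25 regions at 8000001 to 8100000. The window at chromosome 6, 25900001 to 26000000, held 27 regions, the strongest of them at 25947380 to 25949276 with a fold enrichment of 56.9 ± 16.5. The windows at chromosome 2, 19900001 to 20000000, and at chromosome 1, 106200001 to 106300000, held 24 and 23 regions.

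The input level at the summits, the background of each fold enrichment, differed between and within chromosomes. On chromosome 2 it was 1.28 ± 0.00517 times the autosomal mean up to 52.2 Mb and 0.775 ± 0.0106 times beyond (SD, n = 3), and the step was found in each list, at 52.2, 53.0 and 52.9 Mb. Chromosome 3 went from 1.05 ± 0.00846 to 0.763 ± 0.0127 at 60.4 Mb, and chromosome 7 from 1.095 ± 0.00755 to 0.653 ± 0.00773 at 31.3 Mb. On chromosome 1 the level was 0.786 ± 0.0150 up to 24.95 Mb, 1.03 ± 0.00832 up to 152.9 Mb and 0.745 ± 0.0135 beyond, although lists 1, 2 and 3 gave 3, 2 and 3 steps there and the places of these steps differed by 4306 and 6352 kb between lists. Steps on chromosomes 17 and 20 were found in list 3 alone. Whole chromosomes differed too, with 1.39 ± 0.0232 on chromosome 15 and 0.854 ± 0.0185 on chromosome 14. Z had a level of 0.624 ± 0.0130 and W of 0.517 ± 0.0420, but 42.8% of Z peaks and 67.4% of W peaks were at the floor of the input level. A step on Z at 73.2 Mb was found in lists 1 and 2 but not in list 3, with 22.4 regions per Mb up to it and 6.02 beyond. Region density differed across these steps, with 40.3 and 25.9 regions per Mb left and right of the step on chromosome 2, 40.2 and 26.6 on chromosome 3, and 42.6 and 23.1 on chromosome 7. The contrast was smaller on chromosome 1, with 27.7, 33.2 and 25.8 regions per Mb in its 3 parts.

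**Figure D5:**
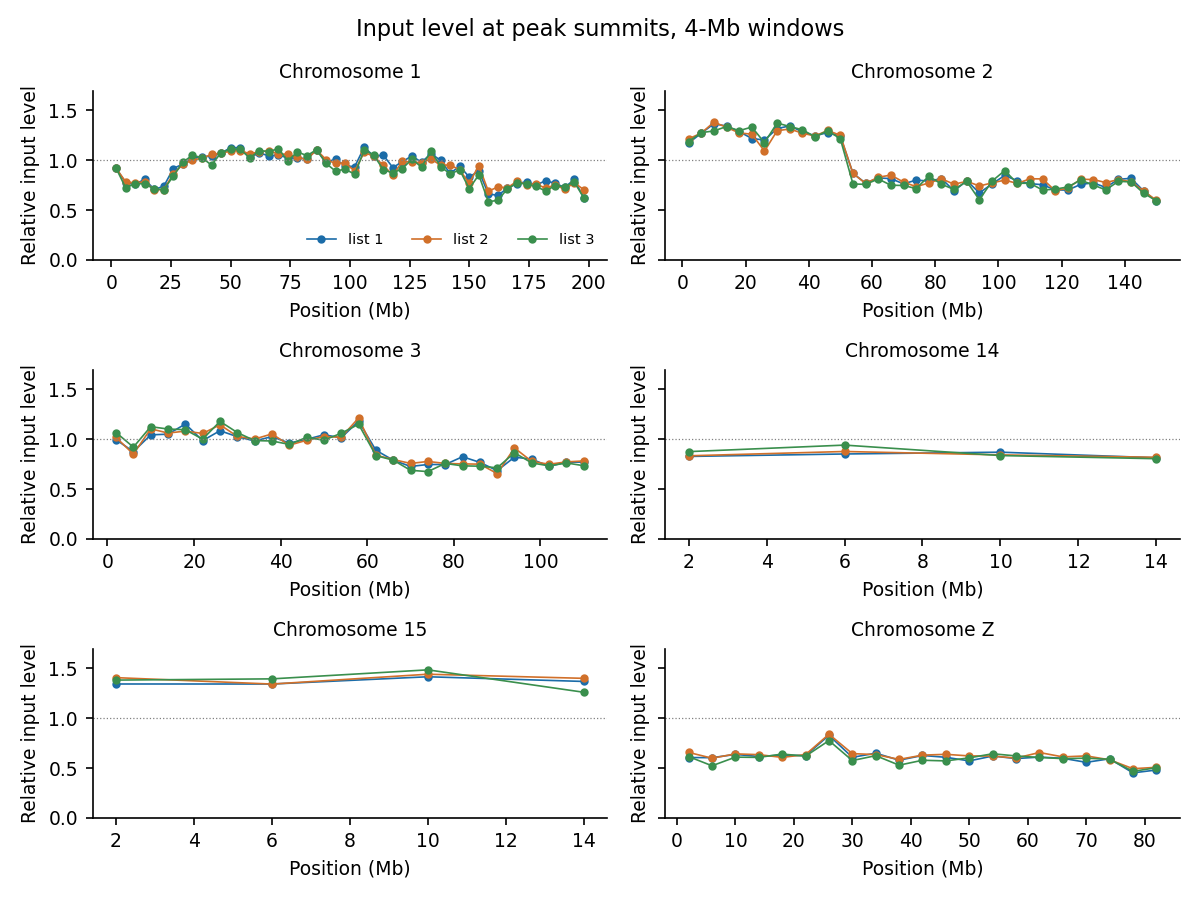
Input level at peak summits relative to the autosomal mean of each list (y axis, a ratio) in windows of 4 Mb along chromosomes 1, 2, 3, 14, 15 and Z (x axis, position in Mb). Each coloured line is a peak list; all 3 fall on chromosome 2 near 52.2 Mb, from a mean of 1.28 to 0.775.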

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

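The q-value limit of 0.05 (run for the number of regions and the overlap), the subset of autosomes and the limit to regions with a fold enrichment of at least 10 were chosen after the data were seen; the other alternatives were set before. The number of reproducible regions stayed within 1.5 times 37420 with a reciprocal overlap of 50% (33962), summits within 100 bp (33597), a q-value of at most 0.05 (35801), and at least 2 of the 3 lists (51317). It was 23796 with a q-value of at most 1e-05 and 21117 in the stronger 50% of each list, where fewer peaks enter. Leaving out each list in turn gave 41311 to 43118 regions shared by the other lists. The overlap between lists, 74.7%, was 66.00% with a reciprocal overlap of 50% and 65.97% with summits within 100 bp, both stricter definitions. It was 80.9% with a q-value of at most 1e-05 and 82.0% in the stronger 50% of each list, and 73.9% to 76.1% without each list. The rank correlation of strength between lists, 0.773, was 0.843 with −log10 p in place of fold enrichment and 0.749 in the stronger 50%; the cause was not tested. It was 0.766 to 0.774 without each list. Reproducible peaks were more enriched under each alternative run, by 2.95 to 4.03 in fold enrichment and by 9.81 in −log10 p. Each alternative still required calls in several lists, so this direction was largely built in there too. The fall of density with chromosome span lost its call in the stronger 50% of each list (rho = −0.298, permutation p = 0.0941), and the cause was not tested. With a q-value of at most 1e-05, at least 2 of the 3 lists, each list left out, regions with a fold enrichment of at least 10, autosomes, or chromosomes of at least 5 Mb, rho was −0.811 to −0.369 with a permutation p under 0.05, but autosomes under 20 Mb alone gave no call (rho = −0.277, permutation p = 0.238), nor did Pearson's r over all 33 chromosomes (adjusted p = 0.0824). Leaving out each list in turn moved the mean fold enrichment of the named region on chromosome 25 from 86.0 to between 66.8 and 111.

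No paired analysis was possible because the lists hold no separate values of the input samples and are not matched to the replicate numbers of the samples. The alternatives planned for the promoter share, the E-box share, the other motifs, the gene lists and the density per gene were not run, since no sequence or gene positions of the build were used here. Sequencing depth is unknown and was not varied. Its effect was weighed only indirectly, through input levels and strong regions, and only for the density of regions on chromosomes. The smallest pileups were 3 or 4 fragments, so the values of weak peaks are coarse.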

Other observations

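At 4 reproducible regions the input level was at least 5 times the autosomal mean in every list, so their high pileups came with a high background. They were at chromosome 3, 95700707 to 95701981 (10.9 ± 1.60 times, SD, n = 3), chromosome 1, 152858918 to 152860063 (10.1 ± 1.57 times), and chromosome Z, 27313321 to 27314127 (9.02 ± 3.22 times) and 27307047 to 27307526 (5.97 ± 0.914 times). Their fold enrichments were 7.13 ± 0.1196, 5.81 ± 1.77, 2.97 ± 1.11 and 6.90 ± 1.42.

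The patterns below were found in these data and tested on them, so every explanation is a hypothesis, and the design offers no biological group to test them against. The tests of a bias that follows chromosome size, of few input reads under each summit and of density between chromosome classes with like input levels were chosen after the result was seen.

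The input level changed in steps along chromosomes 1, 2, 3 and 7 and differed between whole chromosomes. A bias that follows chromosome size is argued against by chromosomes 14 and 15, of similar span, whose levels differed by a ratio of 1.63 ± 0.0177 (SD, n = 3). Selection of summits by the peak caller is argued against by the peaks with the highest −log10 p, which pass the threshold at either level and kept a ratio of 1.63 ± 0.0225 across the step on chromosome 2. A difference in DNA copy number, as in a line with gained or lost chromosome parts, stays open. The median pileup of reproducible regions was higher left of that step by a ratio of 1.32 ± 0.0192. In each list this ratio lay above the bound set beforehand for a copy number difference. Their median fold enrichment changed little (ratio 0.963 ± 0.0349). These values cannot decide the matter, because a peak is called only where its pileup exceeds the input level. A higher input level from any source thus raises the pileup that a peak needs, and the pileup of the strongest peaks alone was not examined. The mean input level of all peaks had a larger ratio (1.65 ± 0.0291), but the pseudocount of 1 dampens its effect on fold enrichment. A bias of sequence composition that acts on both libraries stays open too, since base composition was not measured here.

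Regions were denser on smaller autosomes. For the classes of 5 to 20 Mb and of at least 50 Mb, the class values argue against detection limited by read depth as the whole cause. Their input levels had a ratio of 1.01 ± 0.0124 and their peaks per Mb one of 1.504 ± 0.0152. These levels average unlike parts, so a part played by depth is not excluded. Chromosome 2 beyond 52.2 Mb had a level of 0.775 and 25.9 regions per Mb, whereas chromosome 14 had 0.854 and 50.8. The density ratio of the classes was 1.54 for all reproducible regions and 1.63 for those with a fold enrichment of at least 10 in every list. Among these strong regions, rho with span was −0.451 over 33 chromosomes, short of the −0.5 set beforehand as the bound against this explanation, a bound that the regions as a whole (−0.469) did not reach either, and in the stronger 50% of each list it was −0.298 (permutation p = 0.0941), whereas on chromosomes of at least 5 Mb it was −0.846 for strong regions and −0.811 for all, and a part played by depth stays open for the trend that includes the shorter chromosomes. On Z the strong regions had a density of 0.570 times that on autosomes of at least 50 Mb, and this deficit cannot be told apart from limited depth because 42.8% of Z peaks were at the floor of the input level. The same limit holds for W, where 67.4% of peaks were at the floor. At each of the 5 steps in input level on chromosomes 1, 2, 3 and 7 the side of lower level also had fewer regions per Mb, whereas chromosome 15 had 1.07 times the region density of chromosome 14 at 1.63 times its input level. Gene density, which is known to be higher on small chicken chromosomes, stays open as untested.

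Fold enrichment agreed less well between lists than pileup did at the same region. The rank correlation of pileup exceeded that of fold enrichment by 0.121, and that of the input level itself was 0.381. Few input reads under each summit stay open as an explanation: the gap of 0.121 is the pattern itself and cannot count for it, and read numbers were not used here. After centring each list, the SD between lists was 0.42 for log2 fold enrichment, 0.28 for log2 (pileup + 1) and 0.33 for log2 (input level + 1). Log2 fold enrichment is the pileup term minus the input term, and the input term varied more between lists. What made the input level vary was not tested. At the region on chromosome 25 the input level was 6.72, 1.03 and 1.51 fragments in lists 1, 2 and 3.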
